A study of Mus musculus with 11 samples.

How the data were processed

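The samples were 11 mouse tissue pieces, 5 keratoacanthomas and 6 normal skins, as the labels give them. Per the labels, total RNA was extracted from snap-frozen tissue, amplified by the SPIA method and hybridised as biotin-labelled cDNA to whole-transcript arrays. The deposited table held log2 values of 241576 probesets, for which the labels name RMA, a method with background correction, quantile normalization and probe summary, the Partek software and genome build mm9; their versions and settings were not stated. That the values were log2 was checked on the table, where they ran from 0.994 to 15.2 with array medians of 6.22 to 6.27 and without missing values. The deposited normalization was kept. The labels did not say whether pieces came from separate animals, and no processing batch was given in the sources used here.

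Probesets were assigned to genes by the array's annotation. Of the 241576 probesets, 212097 named 1 gene, 4475 named several and 25004 (10.35%) none; only those naming 1 gene were used, and 590 with values identical to another probeset of the same gene were dropped. The 20416 symbols were updated to current ones where they had changed (2742), 17621 were current and 53 were kept as given. The gene level was the median over a gene's probesets (median 8 per gene, 2275 genes with 1), which gave 20352 genes. Positions of probesets in mm9 were not available, so that no coordinates are given and probesets are ordered by number.

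Tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjusted p below 0.05), and tables and figures Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Keratoacanthoma and normal skin were fitted as 2 groups. A model of 4 groups compared keratoacanthoma with normal skin of the same genotype, normal double with single transgenic skin, K14-Cre only with Zmiz1 only, and the 3 normal genotypes by an F test. Probesets of Zmiz1 were tested with limma, adjusted over its 27 probesets, and with diffSplice. Single measures were compared by exact two-sided permutation tests and intervals are at 95%.

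The 37 gene lists covered the layers of the epidermis, hair follicle, cell division, inflammation, signalling, metabolism and markers of other cell types. They held 793 genes, of which 752 were measured and 14 stood in 2 lists. Lists were tested by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry. Named genes were Zmiz1 and the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap. Also named were up to 4 members past the threshold per described list plus up to 2 in the opposite direction, and the 5 smallest p-values per genotype comparison. Gene models without an official symbol were passed over among the rises and falls. Where a member that this rule names was left out, the text gives the counts of its list; Krt5, Krt14 beside the same-genotype comparison and Zmiz2 were chosen after their values were seen.

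The comparisons, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. These alternatives were the mean over probesets, no dim probesets or dim genes (below the 25th percentile), quantile normalization or centring of the arrays, eBayes with trend and robust, array weights, the title's number as a block, either kind of normal skin alone as reference, a 4-group model with the mean of the 3 normal groups as reference, a fit on the 6 normal arrays, and each array left out. Chosen after seeing the data were fits without the 3 arrays high in hair keratins or with the hair follicle list as a covariate, a test of each probeset minus its gene's median (genes of at least 4 probesets), and the gene families by symbol. Tested on simulated data, the first comparison recovered 30.5% of 82 genes changed by 0.5 on the log2 scale, 85.7% of 56 at 1 and 95.2% of 62 at 2, and called 0.035% of unchanged genes. The same-genotype comparison recovered 1.2%, 51.8% and 90.3%. In the simulated data genes varied independently and 20152 of 20352 were unchanged. The real tumour comparisons called far more genes, so these percentages may not hold for them.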

Results

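Expression was measured on 11 single-colour mouse whole-transcript arrays, each hybridised with amplified cDNA from total RNA of snap-frozen tissue. Of these, 5 held keratoacanthomas, squamous tumours of the skin built of keratinocytes, all from mice carrying both K14-Cre and Zmiz1 transgenes. The other 6 held normal skin, 2 from such double transgenic mice, 2 from mice with K14-Cre only and 2 from mice with the Zmiz1 transgene only. K14-Cre places Cre recombinase under the promoter of keratin 14, a keratin of the basal layer of the epidermis, and Zmiz1 encodes a zinc finger co-activator of transcription related to the PIAS family. The deposited table held log2 values of 241576 probesets, of which 211507 were used for 20352 genes. Array medians lay between 6.22 and 6.27, and the precision was limited by the number of arrays. Correlations over all probesets were 0.943 to 0.960 between keratoacanthomas, 0.890 to 0.950 between normal skins and 0.801 to 0.915 between the groups. The labels did not say whether the pieces came from separate animals, so that p-values measured the spread between these arrays, which may include pieces of the same animal.

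Zmiz1, the transgene, was higher in the tumours. Its gene level, the median over 27 probesets, was 8.15 ± 0.11 (SD, n = 5) in keratoacanthoma and 7.50 ± 0.30 (n = 6) in normal skin. The log2 difference was 0.65 (SE 0.14, limma adjusted p = 0.0045, exact two-sided permutation p = 0.0043), with all 5 tumours above all 6 skins. The probesets did not move together. A run of 14 probesets with consecutive numbers, 10413197 to 10413210, was raised by 2.13 to 3.80 on the log2 scale, while the remaining 13 changed by -0.78 to 0.26. Averaged over the run, the level was 9.75 ± 0.32 in keratoacanthoma and 6.97 ± 0.18 in normal skin, a 6.87-fold difference. Averaged over the other 13 probesets, it was 7.12 ± 0.12 in keratoacanthoma and 7.29 ± 0.06 in normal skin. The 2 sets were chosen by their change between the same arrays, so that these averages describe the sets and do not test them. Of the 27 probesets, 1 was lower past the threshold, with a log2 change of -0.63 (adjusted p over the Zmiz1 probesets 0.0068), and 2 were lower without keratoacanthoma 3, normal skin 2 or normal skin 6.

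Normal skin did not share this run. In the 14 probesets, normal skin of double transgenic mice averaged 6.99 and that of single transgenic mice 6.96, a difference of 0.04 (95% interval -0.43 to 0.50, exact p = 0.93, where 2 against 4 arrays cannot give less than 0.067). At the gene level the difference was -0.16 (95% interval -0.63 to 0.30, limma adjusted p = 0.83). This gene-level difference turned without normal skin 2 (0.08) or 6 (0.0048), with the mean over the probesets (0.04) and without dim probesets (0.07). Of the 27 probesets, 0 passed the limma test between double and single transgenic normal skin (2 at an unadjusted p below 0.05, smallest adjusted p = 0.19). Unequal change among the probesets of Zmiz1 between tumour and normal skin was called by diffSplice (Simes adjusted p = 2.5e-12, rank 87 of 18077 genes by that test and 4 by its F test). That test also called 4.45% of unaltered genes in simulated data, and a test on each probeset minus its gene's median, chosen after the data were seen, gave an adjusted p of 0.00026 (rank 77 of 15543 genes). The gene-level difference depended on the summary, since the mean over the probesets gave 1.36 where the median gave 0.65.

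**Figure D1:**
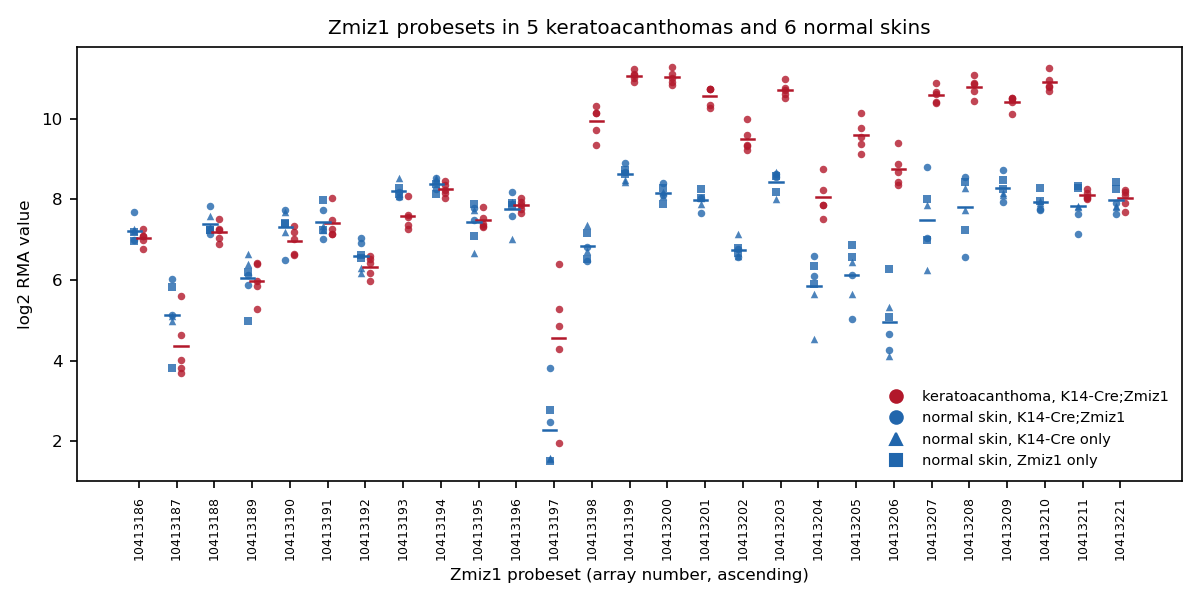
Log2 RMA value (vertical axis) of each of the 27 Zmiz1 probesets (horizontal axis, in ascending probeset number, without positions in the gene) in 5 keratoacanthomas (red) and 6 normal skins (blue, by genotype). Points are arrays and short lines are group means; the probesets from 10413197 to 10413210 averaged 9.75 in keratoacanthoma and 6.97 in normal skin, and the other 13 averaged 7.12 and 7.29.

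The comparison of keratoacanthoma with normal skin, which the series title names, gave broad changes led by genes of stressed epidermis on the higher side and of skeletal muscle on the lower side. Among 20352 genes, 2959 were higher and 2200 lower in keratoacanthoma (limma, adjusted p below 0.05), of which 698 and 518 changed at least 2-fold. The 12 genes with the largest rises included the small proline-rich proteins of the cornified envelope Sprr2f and Sprr2g, raised 33.6-fold and 24.1-fold, and the related pseudogene Sprr2j-ps (44.4-fold). The serine protease inhibitor Serpinb3a rose 39.5-fold, the late cornified envelope gene Lce3b 33.1-fold and the type II transmembrane serine proteases Tmprss11b and Tmprss11g 30.1-fold and 23.4-fold. Further rises were seen for Spink12 (27.4-fold), the neuropeptide precursor Nts (26.6-fold), the antimicrobial beta-defensin Defb4 (21.4-fold), the stefin Csta3 (20.8-fold) and the keratin of hyperproliferative epidermis Krt6b (20.3-fold). Tmprss11b had the smallest p of all genes, at 9.31 ± 0.34 (SD, n = 5) in keratoacanthoma and 4.39 ± 0.26 (n = 6) in normal skin (log2 difference 4.91, SE 0.17, adjusted p = 5.2e-09).

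The 12 largest falls were in genes of striated muscle and its metabolism. The calcium buffer of fast fibres Pvalb was 45.0-fold lower, the fast myosin heavy chains Myh4 and Myh1 37.8-fold and 24.4-fold lower, and the giant sarcomere proteins Ttn and Neb 30.4-fold and 23.6-fold lower. The sarcoplasmic reticulum genes Casq1 and Trdn were 30.3-fold and 28.0-fold lower, the fast troponin C gene Tnnc2 23.6-fold lower, muscle glycogen phosphorylase Pygm 23.4-fold lower and the glycogen phosphatase subunit Ppp1r3a 23.0-fold lower. Cox8b, a respiratory chain subunit of muscle and brown fat, was 33.6-fold lower and the carbonic anhydrase Car3, abundant in muscle and fat, 29.4-fold lower. These 24 were chosen among the 3250 genes (16.0%) in which the 5 tumours and the 6 normal skins did not overlap, where chance separates 0.433%. Members of the Sprr2, Lce3, Krt6, Serpinb3 and stefin families are close in sequence, so that their probes may share signal and their single values are uncertain. The lower group mean lay below the 25th percentile of every array's probesets (4.88 to 4.95) for Sprr2j-ps, Serpinb3a, Lce3b, Tmprss11b, Nts, Sprr2g, Defb4, Trdn and Ppp1r3a, so that these folds depend on dim values and their order is uncertain. With only the normal double transgenic skin as reference the counts became 1942 higher and 1244 lower; no other reference, left-out array or scaling moved either count by over 1.5 times. Of the 124 genes named here as changed, 16 kept their direction but did not pass with that reference, which leaves 7 arrays. They were Krt77 (-2.22, adjusted p = 0.059), Acaca (0.60, 0.071), Aldoa (-0.74, 0.081), Cd207 (-0.49, 0.11), Clec9a (-0.55, 0.064), Dcn (-1.46, 0.11), Dpt (-1.62, 0.12) and Lum (-0.85, 0.20). The others were Dtx4 (-0.41, 0.11), Notch1 (-0.53, 0.056), Gstm1 (-0.60, 0.14), H2-Ab1 (-0.23, 0.33), Mbp (-0.45, 0.20), Pias3 (-0.40, 0.16), Sesn1 (-0.70, 0.065) and Tchh (1.92, 0.20). In the 4-group model, with the same 2 skins as reference, Krt77 (0.032), Notch1 (0.045) and Sesn1 (0.037) passed.

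Within the epidermis, genes of wounded or hyperproliferative skin rose most. Of 33 measured genes of this list, 30 were higher and none lower over all genes, and 32 were higher adjusted over the list alone, with a median log2 change of 3.44 (camera adjusted p = 2.6e-28; adjusted p = 0.080 with an estimated correlation). Its Sprr2, Lce3, Krt6 and stefin members may share signal, and the estimated correlation between its genes was 0.41. The counts are therefore not of independent genes. The list averaged 9.64 ± 0.36 in the 5 tumours and 6.51 ± 0.54 in the 6 normal skins. Of 22 genes of normal spinous and granular differentiation, 11 were higher and 4 lower, with the same counts adjusted over the list alone (median 0.46, adjusted p = 0.0027; adjusted p = 0.32 with an estimated correlation). Repetin (Rptn), caspase 14 (Casp14) and filaggrin (Flg) rose by 4.27, 3.03 and 2.19 on the log2 scale, whereas the suprabasal keratin Krt77 and filaggrin 2 (Flg2) fell by 2.60 and 2.16. Of 19 genes for lipids of the skin barrier, 14 were higher and 1 lower, or 15 and 1 adjusted over the list alone (median 1.06, adjusted p = 8.3e-08; adjusted p = 0.15 with an estimated correlation). Among them were the lipases Lipn (3.21) and Lipk (2.25), the sphingolipid desaturase Degs2 (2.42) and the glucosylceramide synthase Ugcg (1.97).

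Basal and cornified envelope genes went both ways. Of 15 basal genes, 5 were higher and 3 lower, or 8 and 4 adjusted over the list alone, and the list did not pass (median 0.25, adjusted p = 0.28). Integrin alpha 6 (Itga6), keratin 14 (Krt14) and P-cadherin (Cdh3) rose by 1.24, 1.19 and 1.00, and dystonin (Dst), which anchors hemidesmosomes, fell by 1.37; Krt5, the partner of Krt14, differed by 0.25 (adjusted p = 0.095). Of 22 cornified envelope genes, 6 were higher and 5 lower, or 6 and 6 adjusted over the list alone, with a median of -0.15, a mean of 0.19 and no call (adjusted p = 0.99). Transglutaminase 3 (Tgm3), Lce1f, cornifelin (Cnfn) and involucrin (Ivl) rose by 2.12, 1.94, 1.91 and 1.83, and Lce1m and Lce1b fell by 1.41 and 1.19.

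Both lists of cell division genes were higher. All 28 genes of mitosis and the G2 phase were higher, also adjusted over the list alone (median 1.38, adjusted p = 9.1e-16; adjusted p = 0.14 with an estimated correlation), among them Hmmr (2.10), Cenpe (1.97), Bub1 (1.95) and the mitotic kinase gene Cdk1 (1.92). The mitosis list averaged 7.43 ± 0.05 in the 5 tumours; normal skin 1 and 3, the arrays with high hair keratin values described with the cell types, stood at 6.99 and 6.54 and the remaining 4 at 5.64 to 5.87. Of 28 genes of DNA replication, 14 were higher and none lower, or 20 adjusted over the list alone (median 0.54, adjusted p = 9.7e-09; adjusted p = 0.095 with an estimated correlation). The ribonucleotide reductase subunits Rrm2 and Rrm1 rose by 2.37 and 1.15, the helicase subunit Mcm4 by 1.07 and Gins1 by 0.98.

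Growth factor and metabolic genes followed. In the list of EGF receptor ligands and genes induced by RAS and MAPK signalling, 6 of 20 were higher and none lower, also adjusted over the list alone (median 0.21, mean 0.69, adjusted p = 5.8e-05; adjusted p = 0.095 with an estimated correlation). The ligands epigen (Epgn), epiregulin (Ereg) and Hbegf rose by 3.76, 2.11 and 1.88, and the ERK phosphatase Dusp6 by 2.16. Of 26 genes of glycolysis and hypoxia, 19 were higher and 1 lower, also adjusted over the list alone (median 0.66, adjusted p = 1.7e-09; adjusted p = 0.080 with an estimated correlation). Enolase Eno1, the prolyl hydroxylase Egln3, the glucose transporter Slc2a1 and the carbonic anhydrase Car12 rose by 1.74, 1.68, 1.67 and 1.63. The aldolase Aldoa, the form that also prevails in muscle, fell by 0.79. Of 19 genes of cholesterol synthesis, 14 were higher and none lower, or 15 adjusted over the list alone (median 0.84, adjusted p = 2.8e-09; adjusted p = 0.080 with an estimated correlation), with Idi1, squalene epoxidase (Sqle), Cyp51 and Stard4 at 1.70, 1.66, 1.47 and 1.12.

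Shifts were also seen in stress and modifier pathways. Of 17 NRF2 targets and glutathione genes, 6 were higher and 2 lower, or 6 and 3 adjusted over the list alone (median 0.23, adjusted p = 0.019; adjusted p = 0.12 with an estimated correlation). The cystine transporter Slc7a11, Gsta4 and Gpx2 rose by 2.97, 2.88 and 2.45, and Gsta3 and Gstm1 fell by 1.64 and 0.73. Of 13 genes of the PIAS family and the SUMO pathway, 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.51, adjusted p = 0.00044; adjusted p = 0.095 with an estimated correlation). The members that rose, among them the SUMO-activating enzyme subunit Sae1 (1.41), Sumo3 (1.02) and the SUMO proteases Senp2 (0.86) and Senp3 (0.80), were SUMO pathway genes, while Pias3 was lower by 0.63 and the close relative of the transgene Zmiz2 differed by -0.11 (adjusted p = 0.48). Pias3 was not called without dim probesets (-0.23, adjusted p = 0.38) or with the title's number as a block (0.057). Of 19 p53 targets, 7 were higher and 1 lower, or 11 and 2 adjusted over the list alone (median 0.37, adjusted p = 0.046; adjusted p = 0.12 with an estimated correlation), with Mdm2 and Plk2 up by 0.91 and 0.84 and Sesn1 down at -0.91. The p53 target list (p53_targets) was not called without keratoacanthoma 1 (adjusted p = 0.050), keratoacanthoma 3 (0.055), normal skin 2 (0.058) or normal skin 4 (0.053), nor without dim probesets (0.12) or dim genes (0.10) or with only single transgenic skin as reference (0.064). The NRF2 list was not called without dim genes (0.065).

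Inflammatory genes rose as groups. One list held 27 genes, namely cytokines, chemokines and the enzymes Ptgs2, Nos2 and Arg1. Of these, 18 were higher and none lower, or 20 adjusted over the list alone (median 1.18, camera adjusted p = 3.8e-11, or 0.080 with an estimated correlation). The epithelial cytokine Tslp and the prostaglandin synthase Ptgs2 each rose 9.55-fold, Ccl20 7.60-fold and Il19 6.67-fold. Of 24 interferon-stimulated genes, 17 were higher and none lower, or 19 adjusted over the list alone (median 0.88, adjusted p = 3.8e-11; adjusted p = 0.080 with an estimated correlation), led by Isg15 (2.46), Ifi44 (1.98), Oas1a (1.82) and Ifit1 (1.57). Of 24 genes of matrix remodelling, 15 were higher and none lower, or 16 adjusted over the list alone (median 0.82, adjusted p = 1.6e-07; adjusted p = 0.095 with an estimated correlation). The collagenase Mmp13 (3.14), tenascin C (Tnc, 2.79) and the stromelysin Mmp10 (2.30) were among the largest. Neutrophil markers were higher in 8 of 19 genes and lower in none, or 13 adjusted over the list alone (median 0.70, adjusted p = 1.2e-05; adjusted p = 0.17 with an estimated correlation). The chemokine receptor Cxcr2 rose by 3.69, Il1b, also a cytokine of other cells, by 2.22 and Clec4d by 1.79. In the normal skins other than normal skin 1, Cxcr2 stood at 3.99 to 4.46, below the 25th percentile of every array's probesets (4.88 to 4.95). The size of its rise thus depends on dim values.

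Lists of muscle, fat, fibroblast and pericyte genes were lower. All 22 skeletal muscle genes were lower, also adjusted over the list alone (median -4.29, adjusted p = 2.6e-28; adjusted p = 0.080 with an estimated correlation), and the list averaged 6.21 ± 0.63 in the 5 tumours and 10.4 ± 0.49 in the 6 normal skins. Of 19 fat cell genes, 13 were lower and 1 higher, or 14 and 1 adjusted over the list alone (median -0.90, adjusted p = 3.2e-07; adjusted p = 0.15 with an estimated correlation). Adiponectin (Adipoq) fell by 3.49, adipsin (Cfd) by 2.74 and lipoprotein lipase (Lpl) by 2.47, and the lipogenic enzyme Acaca, used by many cell types, was higher by 0.61, or by 0.29 without a call with the mean over probesets (adjusted p = 0.057). Of 24 fibroblast genes, 8 were lower and none higher, or 9 adjusted over the list alone (median -0.40, adjusted p = 0.0064; adjusted p = 0.35 with an estimated correlation). Dpt fell by 2.02, decorin (Dcn) fell by 1.87, lumican (Lum) fell by 1.32 and Cd34 fell by 1.31. Of 12 pericyte and smooth muscle genes, 6 were lower and none higher, or 7 adjusted over the list alone (median -0.44, adjusted p = 0.0060; adjusted p = 0.19 with an estimated correlation). Desmin (Des), which skeletal muscle also holds, fell by 3.15, Synpo2 by 2.08, Myh11 by 1.25 and Lmod1 by 0.84.

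Schwann cell genes were lower in 6 of 11 and higher in none, also adjusted over the list alone (median -0.29, adjusted p = 0.014; adjusted p = 0.15 with an estimated correlation). Cdh19 fell by 1.46, Pmp22 by 1.22, Drp2 by 0.76 and Mbp by 0.69. Pigment cell genes were lower in 2 of 13, or 1 adjusted over the list alone (median -0.37, adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation), the larger fall being that of Mitf by 1.14, a gene that other cells also express. Dendritic and Langerhans cell genes were lower in 4 of 17 and higher in 1, also adjusted over the list alone (median -0.38, adjusted p = 0.046; adjusted p = 0.43 with an estimated correlation). The Langerhans cell marker Cd207 fell by 0.71, the class II gene H2-Ab1 fell by 0.67 and Clec9a fell by 0.59. The dendritic and Langerhans cell list was not called without keratoacanthoma 1 (adjusted p = 0.15), keratoacanthoma 3 (0.055), normal skin 4 (0.052), normal skin 5 (0.088) or normal skin 6 (0.10). Nor was it with double transgenic skin alone as reference (0.67), without dim probesets (0.066) or genes (0.056), with the title's number as a block (0.080) or by fry (0.051). H2-Ab1 did not pass with that block (0.050). The pigment cell list was not called without normal skin 1 (0.057), with the mean over probesets (0.055), without dim probesets (0.090) or without the 3 arrays high in hair keratins (0.062). With double transgenic skin alone as reference, neither the pericyte (0.070) nor the Schwann cell list (0.076) was called. Mbp did not pass without keratoacanthoma 3 (0.061) or 4 (0.053).

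Hair follicle genes set 3 arrays apart without following the groups. The list averaged 8.38 in keratoacanthoma 4, 9.17 in normal skin 1 and 8.96 in normal skin 3, and between 5.78 and 6.30 in the other 8 arrays. Of 40 genes, 2 were higher and 2 lower, or 1 higher and none lower adjusted over the list alone (median -0.44, adjusted p = 0.42). The risers were Dsc2, which is broadly epithelial, by 2.60, and Tchh by 2.98 (adjusted p = 0.040), a call lost without any of the 5 keratoacanthomas or normal skin 2, 4, 5 or 6 (0.069 to 0.083), with trend and robust (0.081) or with the title's number as a block (0.069). Without these 3 arrays, a setting chosen after the data were seen, the list turned and passed (median 0.19, adjusted p = 0.041). Without keratoacanthoma 4 alone it was lower (median -0.79, adjusted p = 0.033). Without the 3 arrays, the first comparison had 2646 genes higher and 2036 lower.

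The remaining lists did not pass. Of 19 Notch pathway genes, 2 were higher and 2 lower, also adjusted over the list alone (median -0.09, mean 0.07, adjusted p = 0.99). Il2ra and Myc rose by 1.81 and 0.62, Dtx4 fell by 0.51, and Notch1 fell by 0.39, a call lost without keratoacanthoma 2 (adjusted p = 0.077) or 5 (0.061) or normal skin 1 (0.052) or 3 (0.051). It was also lost with single transgenic skin alone as reference (0.093), the title's number as a block (0.080) and without the 3 hair keratin arrays (0.074). Of 29 respiratory chain genes, 10 were lower and 2 higher, also adjusted over the list alone (median -0.10, adjusted p = 0.069), led by the subunit forms of muscle Cox8b (-5.07), Cox7a1 (-4.08) and Cox6a2 (-2.87). Of 22 fatty acid oxidation genes, 7 were lower and 2 higher, also adjusted over the list alone (median -0.14, adjusted p = 0.054), the co-activator Ppargc1a falling by 2.46. The skeletal muscle list, with a median of -4.29, was lower in the same arrays. The respiratory chain list passed without keratoacanthoma 5 (0.045) or normal skin 1 (0.036), 3 (0.039) or 4 (0.044), without dim genes (0.039), with double transgenic skin alone as reference (0.0096) and without the 3 hair keratin arrays (0.016). Fatty acid oxidation passed without keratoacanthoma 2 (0.050), 4 (0.047) or 5 (0.027) or normal skin 3 (0.029) or 4 (0.031). It also passed with the mean over probesets (0.020), without dim genes (0.036), with quantile normalization (0.045), with double transgenic skin alone as reference (0.037) and without the 3 hair keratin arrays (0.039). Wnt pathway genes were higher in 2 and lower in 4 of 25, also adjusted over the list alone (median -0.11, adjusted p = 0.24), the Wnt inhibitor Sfrp4 falling by 2.58. TGF-beta and SMAD targets were higher in 6 and lower in 3 of 18, also adjusted over the list alone (median 0.21, adjusted p = 0.18). Genes of epithelial to mesenchymal transition were higher in 2 and lower in 5 of 19, or 5 and 5 adjusted over the list alone. Their median was 0.0033 and their mean 0.02, while the test was in the lower direction (adjusted p = 0.99).

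These lists of other cell types did not pass. Sebaceous gland genes were higher in 2 and lower in 6 of 17, or 2 and 7 adjusted over the list alone (median -0.31, adjusted p = 0.063). The sebaceous list passed without keratoacanthoma 2 (0.044) or 4 (0.043) or normal skin 2 (0.030), without dim probesets (0.026) and without dim genes (0.043). Endothelial genes were higher in 3 and lower in 3 of 18, also adjusted over the list alone (median 0.06, adjusted p = 0.80). Macrophage genes were higher in 2 and lower in 3 of 20, also adjusted over the list alone (median -0.31, adjusted p = 0.28). T and NK cell genes were higher in 1 and lower in 2 of 20, or 1 and 1 adjusted over the list alone (median -0.02, adjusted p = 0.80). Among B and plasma cell genes 1 of 12 was lower, or 0 adjusted over the list alone (median -0.10, adjusted p = 0.60). Mast cell genes were higher in 1 and lower in 1 of 12, or 1 and 3 adjusted over the list alone (median -0.22, adjusted p = 0.42).

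In all, 15 lists were higher and 7 lower by camera with a preset correlation of 0.01 between genes. With the correlation estimated from these arrays 0 passed camera (12 at an unadjusted p below 0.05, smallest adjusted p = 0.080). With the preset correlation, 100 splits of the 11 arrays drawn at random gave a median of 12 called lists. Many such splits kept part of the difference between tumour and skin. By fry, which asks whether a list moves on balance one way and not whether it moves more than other genes, 16 were higher and 10 lower. Among lists not called by camera with the preset correlation, fry called the fatty acid oxidation (0.0060), respiratory chain (0.045), sebaceous (0.024), TGF-beta (0.0085) and Wnt (0.0059) lists.

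**Figure D2:**
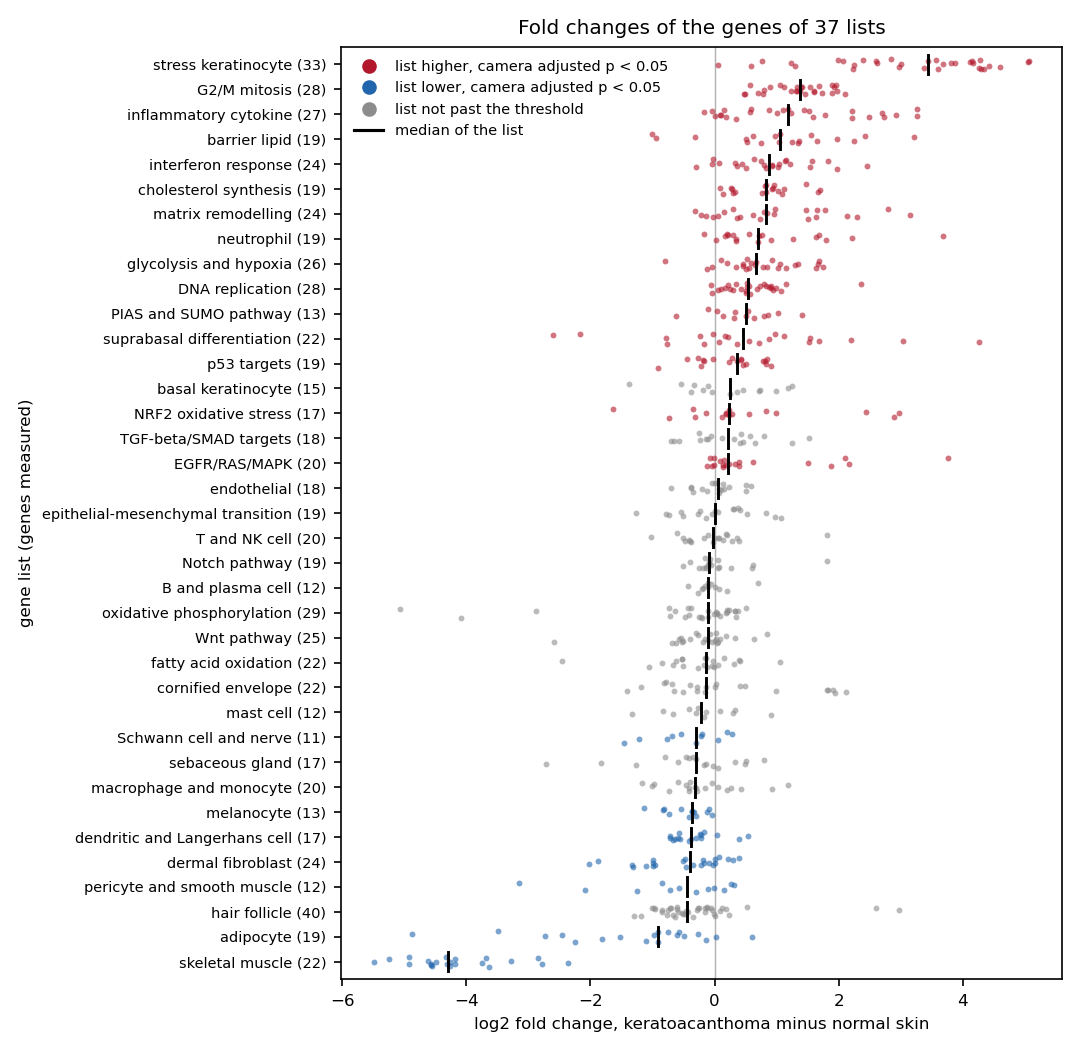
Log2 fold change of each measured gene (horizontal axis, keratoacanthoma minus normal skin, 5 and 6 arrays) in the 37 lists (vertical axis, with the number of genes measured). Points are genes, black bars are list medians and colours mark lists past a camera adjusted p of 0.05; the medians run from -4.29 for skeletal muscle to 3.44 for stress keratinocyte genes.

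**Figure D3:**
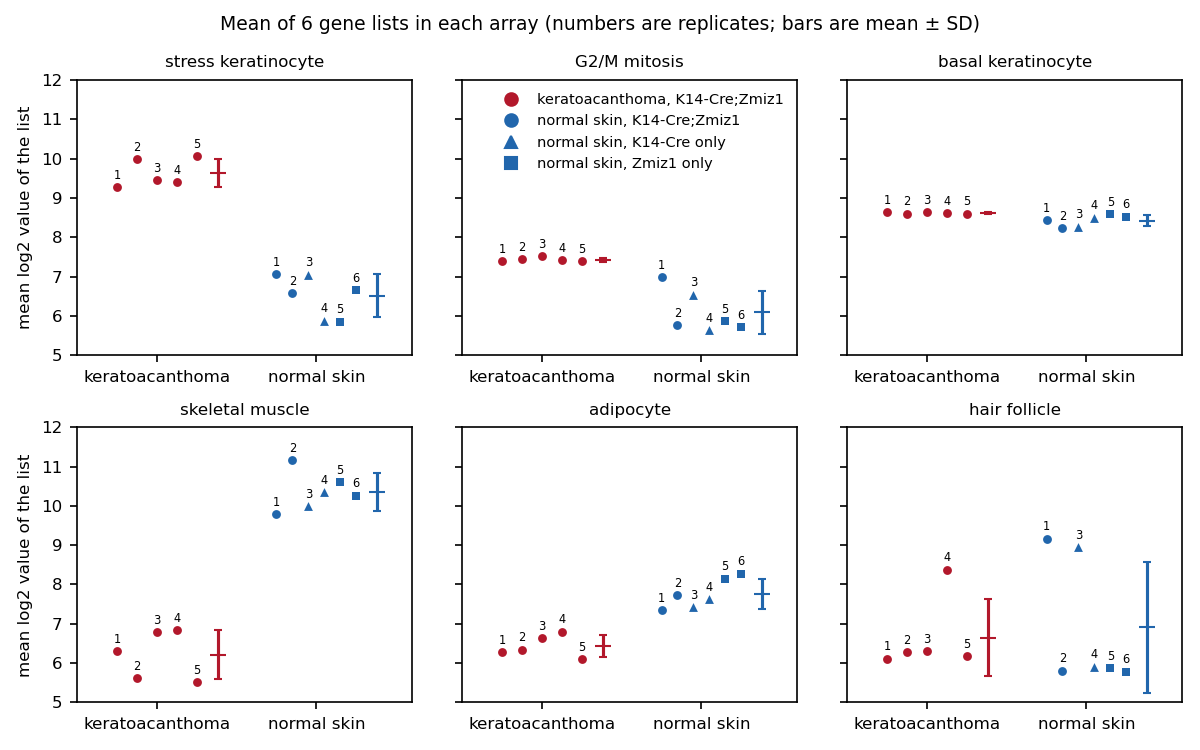
Mean log2 value (vertical axis) of the measured genes of 6 lists in each array, by group (horizontal axis), with the mean ± SD of each group beside the points. Stress keratinocyte and mitosis means were higher in all 5 keratoacanthomas than in all 6 normal skins, skeletal muscle and adipocyte means were lower in all 5, and hair follicle means stood high in keratoacanthoma 4, normal skin 1 and normal skin 3.

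Holding the genotype constant, the 5 keratoacanthomas were compared with the 2 normal skins of double transgenic mice. Here 2164 genes were higher and 1411 lower (limma 4-group model, adjusted p below 0.05), 778 and 509 of them at least 2-fold. The smallest p-values were those of Tmprss11b (log2 difference 5.08, SE 0.24), Epgn (3.64, SE 0.20), the serine protease inhibitor Serpinb2 (2.97, SE 0.18), Teddm3 (3.27, SE 0.22) and, in the other direction, the sarcomere gene Tcap (-4.18, SE 0.28), with adjusted p from 5.9e-06 to 4.3e-05. Zmiz1 was 0.76 higher (SE 0.20, adjusted p = 0.027) and Krt14 1.25 higher (SE 0.21, adjusted p = 0.0037). The 14 raised Zmiz1 probesets averaged 2.76 higher (SE 0.20). Without normal skin 2, 503 genes were higher and 323 lower, but the reference was then 1 array, with the spread taken from the other groups. Array weights, which give less to deviating arrays, left 943 and 492. The lower count became 2301 with the mean over probesets. Without the 3 arrays high in hair keratins, normal skin 2 was the only reference, so the counts of that fit are not given. Both tumour comparisons use the same tumours and share 2 normal arrays, so they are not independent.

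Among normal skins, few genes followed the genotype. Between double and single transgenic skin, 3 of 20352 genes passed (limma, adjusted p = 0.030 for each; 2071 had an unadjusted p below 0.05). The killer cell receptor gene Kir3dl1 was lower in double transgenic skin, at 3.52 against 5.17 (log2 difference -1.65, 95% interval -2.05 to -1.24). Its lower mean lay below the 25th percentile of every array's probesets (4.88 to 4.95), so that the size of this difference is uncertain. The zinc finger gene Zfp345 was higher, at 4.57 against 2.30 (difference 2.27, interval 1.69 to 2.85), but both values were dim and without dim probesets the difference turned to -0.79 (adjusted p = 0.54). The gene 4732465J04Rik was higher, at 6.66 against 4.71 (1.95, 1.44 to 2.47). Across the 3 genotypes, 2 genes passed the F test, Kir3dl1 and Zmat1 (adjusted p = 0.040; 2320 genes had an unadjusted p below 0.05), and between K14-Cre only and Zmiz1 only 0 did (2029 at an unadjusted p below 0.05), where Zmiz1 stood at 7.53 and 7.57. By limma 0 genes differed between double and single transgenic skin without dim probesets, without dim genes, with array weights or in a fit on the 6 normal arrays (1872, 1542, 864 and 1281 at an unadjusted p below 0.05). These counts also moved with single arrays, where a left-out normal skin leaves 1 array of its genotype and the spread comes from the other groups. The first went to 346 genes without normal skin 1, 14 without normal skin 3, 1 without normal skin 2 and 0 without normal skin 4, 5 or 6 or keratoacanthoma 1, 2 or 4. The second went to 125 without normal skin 1, 14 without normal skin 3, 1 without normal skin 5 and 0 without normal skin 6 or any keratoacanthoma. In simulated data with these group sizes, the test of double against single transgenic skin recovered 0% of 82 genes changed by 0.5 on the log2 scale, 50% of 56 at 1 and 88.7% of 62 at 2, so that small differences were not detectable with these arrays.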

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

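The tests of a fault of the 3 arrays, of growing follicles and of an exchanged array were chosen only after the results were seen, as was the fit without these arrays.

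The hair follicle list averaged 8.38 in keratoacanthoma 4, which stood apart from the other 4 keratoacanthomas (6.12 to 6.30), and 9.17 and 8.96 in normal skin 1 and 3. In keratoacanthoma 4 the stress keratinocyte list averaged 9.40, where the highest normal skin stood at 7.07. Its skeletal muscle list averaged 6.84, where the lowest normal skin stood at 9.78. These lists were fixed before the data were examined, and their values argue against an exchange with a normal skin. Its mean in the 14 raised Zmiz1 probesets was 9.35, where the highest normal skin stood at 7.17. Those probesets were chosen with this array among the tumours, so that value is weaker evidence. Growing hair follicles in these pieces stay open as a candidate explanation: the same 3 arrays were the 3 highest in the pigment cell list, at 5.90 to 6.69 against 5.23 to 5.73 in the other 8, which chance gives in 0.606% of cases. A fault of these arrays as a whole was not decided. Within their groups, they were highest in 2 (DNA replication and Wnt) and lowest in 1 (endothelial) of the 35 lists other than the hair and pigment cell lists, 3 where chance gives 0.93. The Wnt list shares Lef1 with the hair follicle list. This count cannot tell a fault of the arrays from a difference between the tissue pieces, so it does not speak for a fault. Age, hair cycle and body site of the mice are not given in the sources used here and stay untested.

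Normal skin 2 stood apart from the other 5 normal skins in 7 measures. Its median correlation with them was 0.894 (others 0.916 to 0.922), and that with the keratoacanthomas 0.832 (others 0.882 to 0.901). Its mean over genes of spinous and granular differentiation was 8.95 (others 9.49 to 9.61), over genes of epithelial to mesenchymal transition 7.25 (others 7.55 to 7.70) and over respiratory chain genes 9.92 (others 9.21 to 9.44). Its Ppargc1a level was 7.36 (others 6.29 to 6.65) and its Sesn1 level 7.21 (others 7.58 to 7.78). The skeletal muscle list was also highest in this array, at 11.2.

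Single values far from the rest of their group were found in 3 other arrays. In keratoacanthoma 1 the macrophage list averaged 6.27 (others 6.94 to 7.13), Flg stood at 11.3 (others 11.6 to 11.8) and Tmprss11b at 8.72 (others 9.35 to 9.57). In keratoacanthoma 4 the Wnt pathway list averaged 6.22 (others 6.03 to 6.05) and Ivl stood at 10.6 (others 10.8 to 10.9). In normal skin 1 Cxcr2 stood at 5.63 (others 3.99 to 4.46) and Hmmr at 6.34 (others 4.43 to 5.04). In all, 15 of 346 sets of values held such an array, where chance gives about 1 in 20.

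Probesets outside the comparisons held no larger share of calls than all probesets. Of the 25004 probesets with no gene symbol, 1601 were higher and 1118 lower in keratoacanthoma, and of the 4475 with several symbols 386 were higher and 277 lower (limma, adjusted p below 0.05 over all probesets). Over all 241576 probesets, 19682 were higher and 16413 lower.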

How the results depend on the processing

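The fits without the 3 arrays high in hair keratins, with the hair follicle list as a covariate and on each probeset minus its gene's median were chosen only after the results were seen. Beside Etfa, given below, 124 genes were named as past the threshold in the first comparison, 122 of them present in the fit without dim genes. Of the 124, 108 kept their call and direction in every setting that held them and 16 lost it in at least 1. Each of these 16 lost it with only the 2 normal double transgenic arrays as reference. That reference gave 1942 genes higher and 1244 lower; fewer arrays were then compared. The Zmiz1 difference of 0.65 ran from 0.58 to 0.73 over the left-out arrays and was 1.36 with the mean over probesets, and its lower probesets numbered 1 to 2 over the left-out arrays. With the title's number as a replicate block, 2596 genes were higher and 1716 lower. Between arrays of the same number, the deviations from the group means correlated at -0.18 to 0.10. These values gave no sign that the numbers pair the arrays, but they cannot exclude it. For all changes below, the cause was not tested.

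Against normal skin of the same genotype, array weights left 943 genes higher and 492 lower. The lower count was 2301 with the mean over probesets and 2271 without the 3 hair keratin arrays, and over the left-out arrays the counts ran from 503 to 2542 higher and from 323 to 2111 lower. Between double and single transgenic normal skin, 0 genes passed without dim probesets, 0 without dim genes, 0 with array weights and 0 in a fit on the 6 normal arrays; 215 passed without the 3 hair keratin arrays and 0 to 346 over the left-out arrays. Between the 3 genotypes, 1 passed without dim probesets, 0 without dim genes, 4 with quantile normalization, 0 with array weights, 29 without the 3 arrays and 0 to 125 over the left-out arrays. The Zmiz1 difference between double and single transgenic skin was 0.037 with the mean over probesets, 0.067 without dim probesets and -0.40 to 0.079 over the left-out arrays. Zfp345 turned to -0.79 without dim probesets.

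With an estimated correlation 0 lists were higher and 0 lower. Directions turned mainly for lists with a median near 0. The cornified envelope list (median -0.15) was tested as lower without dim genes (-0.15), with quantile normalization (-0.16), centred arrays (-0.14), the replicate block (-0.13), single transgenic skin as reference (-0.14) and the covariate (-0.15), and at -0.24 to -0.14 in the left-out arrays that turned it (-0.24 to -0.069 over all 11). The hair follicle list turned to 0.19 without the 3 arrays and ran from -0.79 to -0.014 over left-out arrays, its test turning without normal skin 1 (-0.014) or 3 (-0.042). The endothelial list was 0.057 without dim genes and the T and NK cell list -0.037 with the mean over probesets and -0.00092 without dim probesets. Etfa, a fatty acid oxidation gene at 0.40 (adjusted p = 0.044), was -0.060 with the mean and lost its call without any array but keratoacanthoma 3 or normal skin 2 (adjusted p 0.055 to 0.105), as with the replicate block, double transgenic skin as reference, the covariate and without the 3 arrays. The Notch list was tested as lower with the mean (-0.10), without dim probesets (-0.070) or genes (-0.070), with quantile normalization (-0.093), array weights (-0.092) and single transgenic skin as reference (-0.13), and at -0.13 to -0.075 in the left-out arrays that turned it (-0.13 to -0.025 over all 11). The transition list was tested as higher with the mean (0.0033), without dim probesets (0.026), with the replicate block (-0.0062), double (0.080) or single (0.070) transgenic skin as reference, without the 3 arrays (0.096) and with the covariate (0.015), and at -0.0062 to 0.026 in the left-out arrays that turned it (-0.042 to 0.044 over all 11).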

Other observations

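The tests on Zmiz1 probesets and on tissue shares, and the gene families, were chosen only after the results were seen; the counts over other splits of the arrays were chosen before.

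Genes that share a symbol stem were grouped into 324 families of at least 8 genes, of which 45 were higher and 10 lower in keratoacanthoma by camera with the preset correlation. With an estimated correlation 0 passed (44 at an unadjusted p below 0.05). Beside the small proline-rich proteins (Sprr, 12 of 14 genes higher), the higher families included genes of translation initiation (Eif, 29 of 55 higher, 1 lower, median 0.49), proteasome subunits (Psmd, 14 of 14, median 0.60), the stem Rps, which holds ribosomal proteins, their pseudogenes and Rps6k kinases (18 of 42 higher, 1 lower, median 0.29) and the chaperonin Cct (7 of 9, median 0.71). Also higher were nucleoporins (Nup, 17 of 21, median 0.58) and the ribosome assembly genes Utp (9 of 11, median 0.63) and Nop (7 of 8, median 0.71), and families of other kinds such as the proteases Tmprss (9 of 17, median 0.48). The lower families included the homeobox genes Hoxb (6 of 10, median -0.51), the major urinary proteins Mup (5 of 8, median -1.08) and fibroblast growth factors (Fgf, 7 of 22, median -0.28). Also lower were Myh (6 of 14), Ndufb (5 of 10), Camk (5 of 10), Asb (7 of 18) and Scn (6 of 12). Olfr (34 of 985 lower, 3 higher, median -0.10) and Vmn (13 of 184 lower, 1 higher, median -0.12) passed as well. Their share of lower genes was smaller than that over all genes, where 2200 of 20352 were lower. Some of the lower families, such as the myosins Myh, hold muscle genes, which were lower as a list, and members of Sprr and Mup are close in sequence.

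The 14 raised Zmiz1 probesets and the 13 others point to unequal change within the gene. Binding of Zmiz2 transcripts is argued against, since Zmiz2 differed by -0.11 (95% interval -0.32 to 0.11). A larger share of keratin 14-expressing cells is argued against for the raised probesets: normal double exceeded single transgenic skin by 0.037 (upper bound 0.50), below the 1.51 by which their rise in keratoacanthoma exceeded that of Krt14. A transcript that holds part of the gene stays open. The raised probesets formed 1 run in the order of their numbers, but this restates the pattern and is no separate test. Such a transcript may come from the transgene, whose content is not given in the sources used here. Of the 13 other probesets 11 lay above the median array value in normal skin.

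Less muscle in the tumour pieces may account for the lower muscle genes. All 22 were lower, but this count restates the pattern and is no separate test of the amount of muscle. The mean of the epidermal stress genes minus that of the basal list rose by 2.92 (exact permutation p = 0.0022). For the mitosis genes it rose by 1.15 (exact permutation p = 0.0065). The stress and mitosis lists were already known to be higher in every tumour, so these p-values largely restate the pattern. The basal list is only a mixed measure of the share of keratinocytes. A larger share of basal keratinocytes alone is argued against for the stress genes, whose median of 3.44 lay above all 15 basal genes. The share of suprabasal cells was not tested. The basal genes went both ways (median 0.25, SD 0.72), and all 15 lay below the mitosis median of 1.38. Since Itga6 (1.24), Krt14 (1.19) and Cdh3 (1.00) came near it, a larger share of keratinocytes stays open for the mitosis rise. Other differences between tumour and skin stay untested.

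Of the 462 splits of the 11 arrays into 5 and 6, 100 were drawn. The real split gave 5159 genes, 1216 of them at least 2-fold, and only 1 split, the real one, gave as many of either; the highest others were 784 and 331 genes. For gene lists the real split gave 22, the highest other 23, and 3 of the 100 splits gave as many. At this number of splits the real split stood apart clearly in the 2 gene counts and only narrowly in the list count, where 2 other splits gave more. Those 2 held 0 and 1 keratoacanthomas in the group of 5, so they lay near the reverse of the real split. Since other splits keep part of the difference between tumour and skin, these counts do not exclude chance. The other splits had a median of 12 lists and 0 genes, so that camera with a preset correlation often called lists where no gene passed. The split with 784 genes set 5 normal skins against the 5 keratoacanthomas and 1 normal skin.

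The highest value of the table, 15.2, belonged to probeset 10398543, in keratoacanthoma 4; the other arrays stood at 6.20 to 7.53 there. Of the 3 genes that differed between double and single transgenic skin, the keratoacanthomas, also double transgenic, followed the double transgenic skins in 1. They stood at 7.14 to 7.79 in 4732465J04Rik (double transgenic skins 6.93 and 6.39, single 4.49 to 5.01). In Zfp345 they stood at 2.21 to 2.67 (5.13 and 4.02, single 1.89 to 2.79) and in Kir3dl1 at 4.83 to 5.28 (3.44 and 3.61, single 4.48 to 5.63).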
